A study of Mus musculus with 45 samples.

How the data were processed

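RNA from liver, skeletal muscle and epididymal fat of B6 and 129S6 mice was measured on Affymetrix arrays with 1 colour, 45 in all. Per the labels, each array carried biotin-labelled cRNA made from 25 µg of total RNA pooled from 2 to 3 mice, so a p-value measures the spread between pools. The deposited values are on the log2 scale, made by the authors with RMA, which subtracts background, equalises the distributions of the arrays and summarises the probes of each probe set; the version of the software is not given in the sources used here. The table held 12488 probe sets without missing values, from 2.26 to 14.26, and array medians from 6.08 to 6.24.

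Of the probe sets, 66 were controls, 10833 carried 1 gene symbol, 396 several and 1193 none. Only those with 1 symbol were tested; 10817 of them were matched to the reference table by Entrez gene ID and 16 were not. For each gene the probe set with the highest mean over the arrays of the tissue was kept, which left 8251 genes. Samples were grouped by tissue, strain and diet into 12 groups. Runs of array numbers in the sample names split the liver arrays into 3 series, L1 to L3, and the fat arrays into 2, F1 and F2. Whether the arrays of a run were hybridised together is not given in the sources used here, so the block stands for the run of numbers alone. L1 held the B6 low-fat arrays alone. L2 held 129S6 low-fat replicates 5 and 6 and the 129S6 high-fat arrays. L3 held 129S6 low-fat replicates 11 and 12 and the B6 high-fat arrays. F1 held the B6 arrays and 129S6 low-fat replicate 9, and F2 held the other 129S6 arrays.

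Each tissue was fitted apart with limma 3.58.1 in R 4.3.3, with a mean for each of its 4 groups and moderated variances. The tests were two-sided, adjusted by Benjamini and Hochberg over the genes of a comparison, with an adjusted p threshold of 0.05. The comparisons were diet within each strain, strain on each diet, the diet difference in B6 minus that in 129S6, and the strain difference averaged over the diets. Counts of shared genes are given beside the number expected of independent lists. Gene lists, 38 in all and fixed before the data were examined with at least 4 measured members, were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the 28, 26 and 27 lists of liver, muscle and fat. The lists given for each comparison were chosen after the values were seen and by no fixed rule, so the number of lists that passed is given beside them. Measures of array quality were compared by exact permutation tests, adjusted over 36 comparisons. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

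The genes named follow a rule set before the data were examined. For each diet and strain comparison these are the 8 largest differences each way among genes past the threshold whose groups do not overlap, up to 3 members of each list with the smallest adjusted p past the threshold, and a short list of genes fixed beforehand. For the test of the difference between the strains they are the 5 largest each way, and for comparisons with fewer than 3 genes past the threshold the 3 with the smallest p each way. For calls shared by the tissues they are the 6 each way with the largest smallest difference. The text may name fewer, in the order of the rule, and omits some of the short list. Where another probe set of a named gene, above 4.5 log2 units on average, did not pass in the same direction, its value is given. Outside the rule, the values of Srebf1, Fasn, Pltp and Scd1 in liver for the test of the difference between the strains are given because these genes are named for diet in 129S6.

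The alternatives set before the data were examined were all probe sets, probe sets specific to 1 gene, the genes without the dimmest part (1 in 3), quantile normalization within a tissue, a fit of only the 2 groups compared, an intensity trend with a robust prior, the array series as a block and leaving out each array in turn. Others were added after the data were seen: the 3' to 5' signal of control probe sets as a covariate, leaving out arrays with a Gapdh 3' minus 5' signal above 3, the SD of each muscle and liver array as a covariate, the arrays of 1 series alone, and list shifts under the block and these covariates. The pipeline was tested on simulated data with 200 changed genes among 8251.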

Results

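Gene expression was measured in liver, skeletal muscle and epididymal fat of mice of 2 inbred strains, C57Bl/6 (B6) and 129S6/SvEvTac (129S6), on a low-fat or a high-fat diet. The mice were 6 months old. Each of the 45 arrays carried labelled cRNA made from RNA pooled from 2 to 3 mice, so that the spread between arrays is the spread between pools. Liver had 4 arrays in each of its 4 groups. Muscle had 3 arrays of B6 mice on the low-fat diet and 4 in each other group, and fat had 4 arrays in each B6 group and 3 in each 129S6 group. The design text describes 1 diet, in which carbohydrate gave 57% of the calories, protein 22% and fat 21%. Which of the 2 diets it was, and the composition of the other, are not given in the sources used here. The number of arrays limits the precision of every difference. The design implies the question of how the response to dietary fat in each tissue depends on the genetic background, and how the strains differ on each diet. A diet difference below is high-fat minus low-fat and a strain difference is B6 minus 129S6, each given in log2 units ± SE with the adjusted p of limma over 8251 genes.

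In the liver of B6 mice, the high-fat diet came with lower expression of many oxidative phosphorylation genes and of some male-biased liver genes, drug-metabolising enzymes and ribosomal proteins. Hsd3b5, a hydroxysteroid dehydrogenase typical of male mouse liver, had the largest fall, from a mean of 9.14 log2 units to 5.24, a difference of -3.89 ± 0.41 (n = 4 and 4 arrays, adjusted p = 2.33e-05). Of 10 measured genes of urinary proteins and male-biased liver expression, 5 fell, 6 when adjusted over the list alone. Among them were Elovl3, a fatty acid elongase (-1.12 ± 0.17), and the growth factor Igf1 (-0.59 ± 0.13; -0.30, adjusted p = 0.0759, after quantile normalization and -0.36 with the 3' to 5' signal as a covariate). Of 41 drug-metabolising enzymes, 19 fell and 1 rose, 20 and 1 when adjusted over the list alone. The differences included Gstm6 at -0.81 ± 0.08, Cyp1a2 at -1.21 ± 0.15 and Gstt1 at -0.72 ± 0.10 (-0.40 after quantile normalization). Of 72 oxidative phosphorylation genes, 46 fell and 1 rose, 52 and 1 when adjusted over the list alone. They were led by the succinate dehydrogenase subunits Sdhc (-0.93 ± 0.09) and Sdhb (-0.73 ± 0.08) and the complex III subunit Uqcr11 (-0.89 ± 0.10), at -0.62, -0.42 and -0.58 after quantile normalization. Of 37 ribosomal protein genes, 15 fell and 2 rose, 17 and 2 when adjusted over the list alone. These 4 lists shifted down by the camera test (adjusted p = 0.00443, 1.66e-06, 2.77e-16 and 8.63e-05 in the order given) and each had adjusted p = 0.048 with an estimated correlation. After quantile normalization they stayed past the threshold with smaller mean differences, -0.68 in place of -0.78, -0.24 in place of -0.38, -0.28 in place of -0.45 and -0.155 in place of -0.28. Of 40 proteasome genes, 14 fell, 17 when adjusted over the list alone, a shift with an adjusted p of 4.52e-06 by camera and adjusted p = 0.382 with an estimated correlation. Its mean difference went from -0.30 to -0.17 after quantile normalization and to -0.175 with the 3' to 5' signal of control probe sets as a covariate. Extracellular matrix genes went the other way, with 9 of 37 higher and 1 lower, 14 and 2 when adjusted over the list alone (adjusted p = 0.00197, and adjusted p = 0.0905 with an estimated correlation). Of 21 skeletal muscle genes 3 rose and 1 fell (adjusted p = 0.00969, and adjusted p = 0.461 with an estimated correlation). The 3 were Tnnc2 (0.50 ± 0.12; -0.04 by another probe set, adjusted p = 0.869 over all probe sets), Pvalb (0.53 ± 0.13) and Ckm (0.30 ± 0.09; adjusted p = 0.0608 after quantile normalization and 0.118 with the 3' to 5' signal as a covariate), and the muscle actin Acta1 was at 9.57 in B6 high-fat replicate 13. None of the 17 fatty acid synthesis genes passed limma's threshold, over all genes or adjusted over the list alone, and 3 had an unadjusted p under 0.05. Fasn, the fatty acid synthase, differed by 0.00 ± 0.15 and Scd1, the stearoyl-CoA desaturase, by 0.61 ± 0.21 (adjusted p = 0.0589). Scd1 did pass after quantile normalization (0.82, adjusted p = 0.00503), with only the 2 groups in the fit (adjusted p = 0.00405), without the arrays of high 3' to 5' signal (adjusted p = 0.0272), and with that signal (0.85, adjusted p = 0.0111) or the array spread (1.23, adjusted p = 0.00421) as a covariate. A second Scd1 probe set gave 0.58 ± 0.22 (adjusted p = 0.0765 over all probe sets). The dimmest of 3 Scd1 probe sets, at a mean of 8.74 against 11.84 log2 units, differed by -0.62 ± 0.19 (adjusted p = 0.0353 over all probe sets). Another probe set of Igf1 gave -0.44 ± 0.15 (adjusted p = 0.0504).

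The largest increases in B6 liver were in the apolipoprotein gene Apoa4, from 9.58 ± 0.53 to 11.99 ± 0.12 log2 units (SD, n = 4 arrays each), Cd99 (2.19 ± 0.27), the lipid-sensing nuclear receptor Ppara (2.09 ± 0.43), Gsdme (2.06 ± 0.44), the peroxisomal gene Pex11a (1.96 ± 0.43), the class I histocompatibility gene H2-Q1 (1.67 ± 0.11), Dhx36 (1.60 ± 0.36) and the basement membrane collagen Col4a1 (1.52 ± 0.23). Another probe set of Gsdme, at a mean of 4.90 against 5.56 log2 units, differed by 0.004 (adjusted p = 0.986 over all probe sets). After Hsd3b5, the largest decreases were in Sod1, the cytosolic superoxide dismutase (-2.35 ± 0.40), the adipokine gene Serpina12 (-2.21 ± 0.28), Hsd11b1, which regenerates active glucocorticoid (-1.40 ± 0.14), Keg1 (-1.35 ± 0.26), Car14 (-1.35 ± 0.09), the glutathione transferase Gsta2 (-1.34 ± 0.20) and Hsd17b2 (-1.34 ± 0.11). In all, limma called 1502 genes, 512 higher and 990 lower. Of the 28 lists, 12 passed camera, 4 of them also with an estimated correlation. The Gapdh control probe sets, whose 3' minus 5' signal rises as RNA degrades, gave 1.257 ± 0.44 in the low-fat arrays and 0.296 ± 0.052 in the high-fat arrays (SD, n = 4 each; exact permutation test, two-sided p = 0.0286, the smallest possible, 0.129 after adjustment over 36 such comparisons). The low-fat arrays also had the wider spread over probe sets, with an SD of 1.937 ± 0.032 against 1.854 ± 0.019 (exact permutation test, p = 0.0286, 0.129 after adjustment). With the array spread as a covariate 1047 genes were called, 495 higher and 552 lower. Of those named, Igf1 (-0.33), Keg1 (-0.67), Pvalb (0.20), Ckm (0.15), Tnnc2 (0.47), Pex11a (1.79) and Ppara (1.61) lost their call. The mean differences of the drug-metabolising, oxidative phosphorylation and proteasome lists were -0.235, -0.28 and 0.05 with it, the last with adjusted p = 0.679. The male-biased and the skeletal muscle list had adjusted p = 0.0559 each. All B6 low-fat liver arrays form series L1, a run of array numbers with no other group, so series and group cannot be told apart in any comparison with that group. Without B6 low-fat replicate 4 the count was 842. Of 27 called genes with a difference given here, 26 stayed past the threshold whichever array was left out, and Ckm did not.

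In the liver of 129S6 mice, the high-fat diet came with higher expression of some fatty acid synthesis genes (3 of 17) and lower expression of some drug-metabolising enzymes (7 of 41). The shift of the former list was not called with an estimated correlation (adjusted p = 0.0791). Scd1 rose from 10.46 ± 0.53 to 11.66 ± 0.33 log2 units (SD, n = 4 arrays each; 1.20 ± 0.21, adjusted p = 0.028), Fasn by 0.80 ± 0.15 (adjusted p = 0.0344), and Srebf1, a transcription factor that drives lipid synthesis, by 0.77 ± 0.12 (adjusted p = 0.0232). The dimmest Scd1 probe set gave -0.08 ± 0.19 (adjusted p = 0.959 over all probe sets). The phospholipid transfer protein gene Pltp (0.90 ± 0.17) and the steroid hydroxylase Cyp17a1 (0.66 ± 0.11) also rose. The cytochromes P450 Cyp3a11 (-1.79 ± 0.17, adjusted p = 3.34e-05) and Cyp2b10 (-1.55 ± 0.13, adjusted p = 1.35e-05), which oxidise drugs and other foreign compounds, had the largest falls. They were followed by Serpina12 (-1.44 ± 0.28), Csad, an enzyme of taurine synthesis (-1.41 ± 0.24), the cytokine receptor Lifr (-1.03 ± 0.19), Gsta2 (-0.98 ± 0.20), Aox1 (-0.90 ± 0.15) and Cyp2c70 (-0.85 ± 0.15). None of the 4 other Lifr probe sets passed, and the 3 brightest gave -1.02 ± 0.215 (adjusted p = 0.0866), -0.49 ± 0.27 (adjusted p = 0.849) and -0.01 (adjusted p = 0.995). Adjusted over the list alone, 6 fatty acid synthesis genes rose and 1 fell (camera adjusted p = 4.23e-05). Of the drug-metabolising enzymes 11 fell when adjusted over the list alone (adjusted p = 4.95e-10, and 0.0383 with an estimated correlation). None of the 10 genes of urinary proteins and male-biased liver expression passed limma's threshold, over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05. All 10 differences were negative and the list shifted down (adjusted p = 0.00225, and 0.0383 with an estimated correlation).

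Limma called 19 genes for diet in 129S6 liver, 5 higher and 14 lower, and 527 had an unadjusted p under 0.05. Of the lists, 10 passed camera, 2 of them also with an estimated correlation. With the array series as a block the count of genes was 10, with 8 higher and 2 lower, and within series L2, which holds 2 of the low-fat and all high-fat arrays, it was 12. Of the 13 called genes with a difference given here, Scd1, Srebf1, Cyp3a11 and Cyp2b10 stayed past the threshold under the block. The other 9 did not: Fasn (0.90, adjusted p = 0.0625), Pltp (0.95, adjusted p = 0.165), Serpina12 (-1.52, adjusted p = 0.21), Csad (-1.02, adjusted p = 0.216), Aox1 (-0.59), Cyp17a1 (0.55), Cyp2c70 (-0.62), Lifr (-0.73) and Gsta2 (-0.56). With only the 2 groups in the fit all but Serpina12, Cyp3a11 and Cyp2b10 lost their call. Lifr (-0.905), Pltp (0.89) and Serpina12 (-1.47) lost it with the 3' to 5' signal as a covariate. These and Gsta2 did without the arrays of high signal (Gsta2 -0.77) and with all probe sets. Gsta2 and Serpina12 did with an intensity trend, and Fasn after quantile normalization (adjusted p = 0.0526). The count was 31 with the array spread as a covariate, 11 higher and 20 lower. The shifts of the fatty acid synthesis and drug-metabolising lists had adjusted p = 1.53e-06 and 0.00041 by camera under the block, and that of the male-biased list had adjusted p = 0.078. The mean differences of the latter 2 went from -0.29 to -0.185 and from -0.30 to -0.19. Without low-fat replicate 11 there were 8 higher and 7 lower. The count fell to 6 without 129S6 low-fat replicate 12, and to 2, 3, 7 and 2 without high-fat replicates 7, 8, 9 and 10. Of the 19 genes, 12 were called in the same direction in B6 liver, 1 higher and 11 lower, where independent lists would share 0.31 and 1.68. This number was 7 and 2 without 129S6 low-fat replicates 11 and 12 and 2, 2, 5 and 2 without high-fat replicates 7, 8, 9 and 10. Of those 13, Cyp3a11 and Cyp2b10 stayed past the threshold whichever array was left out. Over all genes, which are not independent replicates, the diet differences in the 2 strains had a Pearson correlation of 0.123.

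The diet difference in liver itself differed between the strains for 453 genes, 71 with a more positive difference in B6 and 382 with a more negative one. The largest positive values, for diet in B6 minus diet in 129S6, were in Col4a1 (1.94 ± 0.33), H2-Q1 (1.76 ± 0.16), Apoa4 (1.59 ± 0.26), Cd99 (1.499 ± 0.39) and the gap junction gene Gja1 (1.29 ± 0.28). The largest negative values were in the cytoskeletal actin Actb (-3.78 ± 0.82), Hsd3b5 (-3.05 ± 0.59), Sod1 (-2.01 ± 0.57), Sec14l2 (-1.71 ± 0.30) and the lipogenic regulator Mid1ip1 (-1.51 ± 0.26). Another probe set of Mid1ip1, at a mean of 7.43 against 8.06 log2 units, gave 0.10 ± 0.26 (adjusted p = 0.865 over all probe sets), and another of Actb gave -2.27 ± 0.99 (adjusted p = 0.211). Among genes named above for diet in 129S6, and chosen after their values were seen, Srebf1 (-0.87 ± 0.17, adjusted p = 0.00777), Fasn (-0.80 ± 0.21, adjusted p = 0.033) and Pltp (-0.94 ± 0.24, adjusted p = 0.0318) passed this test and Scd1 did not (-0.60 ± 0.30, adjusted p = 0.272). After quantile normalization Srebf1 (-0.605, adjusted p = 0.0847), Fasn (-0.48, adjusted p = 0.268), Pltp (-0.71, adjusted p = 0.109) and Sod1 (-1.81, adjusted p = 0.0917) did not pass. Pltp, Sod1 and Cd99 did not with the array spread as a covariate, where Scd1 was at 0.07. Sod1 also lost its call with all probe sets and with an intensity trend. The other 2 Scd1 probe sets gave -1.04 ± 0.31 (adjusted p = 0.0645 over all probe sets) and -0.54 ± 0.27 (adjusted p = 0.272). Of the 72 oxidative phosphorylation genes, 25 had a more negative diet difference in B6, and 36 more negative and 1 more positive when adjusted over the list alone (camera adjusted p = 6.84e-14, and adjusted p = 0.215 with an estimated correlation). The mean difference of this list went from -0.43 to -0.26 after quantile normalization and to -0.245 with the array spread as a covariate. Among the 28 lists, 8 passed camera and 0 with an estimated correlation. The count of 453 genes was 849 without 129S6 low-fat replicate 11, whose Gapdh 3' minus 5' signal was 3.264, and 267, 298, 299 and 263 without B6 low-fat replicate 4, B6 high-fat replicate 15 and 129S6 high-fat replicates 8 and 9. It was 1073 with the 3' to 5' signal as a covariate and 283 after quantile normalization. With the array spread as a covariate it was 913, and the balance turned, with 485 more positive in B6 and 428 more negative.

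Between the strains, B6 liver had the higher expression of many lipid droplet and steatosis genes and of some fatty acid synthesis genes on both diets. Cidea, a lipid droplet protein, was at 9.33 ± 0.57 log2 units in B6 and 5.82 ± 0.10 in 129S6 mice on the low-fat diet and at 10.10 ± 0.27 and 5.89 ± 0.18 on the high-fat diet (SD, n = 4 arrays each), differences of 3.51 ± 0.21 (adjusted p = 8.23e-09) and 4.21 ± 0.21 (adjusted p = 5.44e-10). On the low-fat diet 7 of 11 genes of lipid droplets and steatosis were higher in B6, 8 when adjusted over the list alone, with Pltp at 2.79 ± 0.17 and Cidec at 1.33 ± 0.14. On the high-fat diet 6 were, again 8 when adjusted over the list alone, with Cidec at 1.75 ± 0.14 and Plin4 at 1.11 ± 0.10. Of the 17 fatty acid synthesis genes, 10 were higher in B6 on the low-fat diet and 6 on the high-fat diet, 13 and 9 when adjusted over the list alone. Fasn differed by 1.97 ± 0.15 and 1.17 ± 0.15, Elovl6 by 1.63 ± 0.22 and 1.33 ± 0.22, and Scd1 by 1.85 ± 0.21 and 1.26 ± 0.21. The dimmest Scd1 probe set gave 0.29 (adjusted p = 0.326 over all probe sets) and -0.25 (adjusted p = 0.531). Me1 differed by 1.71 ± 0.25 on the high-fat diet (0.95, adjusted p = 0.198, with the array series as a block). Both lists passed camera on both diets (adjusted p between 8.46e-12 and 9.43e-08). They also passed with an estimated correlation, the lipid droplet and steatosis list at 0.0339 and 0.00759 and the fatty acid synthesis list at 0.0339 and 0.0268. On the low-fat diet 38 of 72 oxidative phosphorylation genes were higher in B6 and 1 lower, 46 and 4 when adjusted over the list alone (adjusted p = 4.61e-12, and adjusted p = 0.119 with an estimated correlation). The mean difference of this list went from 0.36 to 0.20 after quantile normalization and to 0.19 with the array spread as a covariate. On the high-fat diet 8 of 26 interferon response genes were higher and 1 lower in B6, 10 and 1 when adjusted over the list alone. Ifit1 was at 0.77 ± 0.12 and Ifi204 at 1.05 ± 0.19 (list adjusted p = 7.48e-08, and adjusted p = 0.465 with an estimated correlation). Another Ifi204 probe set, at 4.79 against 6.25 log2 units, gave 0.08 (adjusted p = 0.754). There 3 of 32 macrophage genes were higher, 7 higher and 1 lower when adjusted over the list alone. Mmp12 was at 0.66 ± 0.14, Mpeg1 at 1.23 ± 0.31 and Ctss at 1.41 ± 0.39 (list adjusted p = 2.07e-05, and adjusted p = 0.681 with an estimated correlation).

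Other genes with large strain differences in liver on the low-fat diet were the fibrinogen chain Fga (3.33 ± 0.13), 0610005C13Rik (3.31 ± 0.12), the lectin Lgals1 (3.29 ± 0.09), the snoRNA host gene Gas5 (3.15 ± 0.25), the pantetheinase Vnn1 (2.78 ± 0.31) and Serpina12 (2.56 ± 0.28), all higher in B6. Gdpd3 (-2.38 ± 0.22), Apoa4 (-2.05 ± 0.18), Cyp2c39 (-2.02 ± 0.10), Asic5 (-1.75 ± 0.20), Ssr1 (-1.73 ± 0.19) and Hsd3b2 (-1.57 ± 0.28) were lower. Another Ssr1 probe set, at 5.01 against 6.94 log2 units, gave -0.01 (adjusted p = 0.964 over all probe sets). On the high-fat diet Lgals1 (3.15 ± 0.09), Fga (3.03 ± 0.13), Spg21 (2.97 ± 0.32), Gas5 (2.84 ± 0.25), 0610005C13Rik (2.39 ± 0.12) and H2-Q1 (2.15 ± 0.11) were higher in B6. Hsd3b5 (-2.99 ± 0.41), the pentraxin Apcs (-2.22 ± 0.25), Actb (-2.22 ± 0.58), Cyp2c39 (-2.21 ± 0.10), Hsd3b2 (-1.95 ± 0.28) and Gdpd3 (-1.89 ± 0.22) were lower. Another Actb probe set gave -1.81 ± 0.70 (adjusted p = 0.18). Limma called 1142 genes on the low-fat diet, 826 higher and 316 lower in B6. It called 426 on the high-fat diet, 250 higher and 176 lower. Of the 28 lists, 7 and 8 passed camera on the low-fat and the high-fat diet, and 2 each with an estimated correlation. Of the called genes, 155 were called on both diets in the same direction, 116 higher and 39 lower, where independent lists would share 25.0 and 6.74. Another 36 were called in opposite directions. After quantile normalization the low-fat split was 560 higher and 342 lower. The B6 low-fat arrays had the wider spread here too, with an SD of 1.937 ± 0.032 against 1.854 ± 0.041 (n = 4 each; exact permutation test, p = 0.0286, 0.129 after adjustment). With the array spread as a covariate the low-fat count was 462, 232 higher and 230 lower, the high-fat count was 887, and all genes named for either diet kept their call, with Scd1 at 1.23 on the low-fat diet. The low-fat count was 560 without B6 low-fat replicate 4 and 1933 without 129S6 low-fat replicate 11. On the high-fat diet the B6 arrays are all in series L3 and the 129S6 arrays all in L2. With the series as a block, which the 129S6 low-fat arrays of both series allow, 167 genes were called, 46 higher and 121 lower. The lipid droplet and steatosis and the fatty acid synthesis shifts had adjusted p = 3.88e-08 and 0.00257 by camera under it, and the interferon and macrophage shifts 0.0204 and 0.0176. The mean difference of the interferon list went from 0.53 to 0.34. Cidea, Cidec, Plin4, Lgals1 and Fga stayed past the threshold under the block, as did Mmp12 (1.16 in place of 0.66), Spg21 (1.76 in place of 2.97) and Hsd3b2 (-3.24 in place of -1.95). Fasn (0.96, adjusted p = 0.0525), Elovl6 (1.15, adjusted p = 0.124), Scd1 (0.43, adjusted p = 0.423) and Actb (-0.63, adjusted p = 0.72) did not. Nor did Ifit1 (0.55, adjusted p = 0.164), Ifi204 (0.63, adjusted p = 0.289), Mpeg1 (0.91, adjusted p = 0.383) and Ctss (0.44, adjusted p = 0.709). Ctss also lost its call with all probe sets (adjusted p = 0.0503), and Ctss and Actb did with an intensity trend. With each array left out the high-fat count ranged from 249 to 319.

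**Figure D1:**
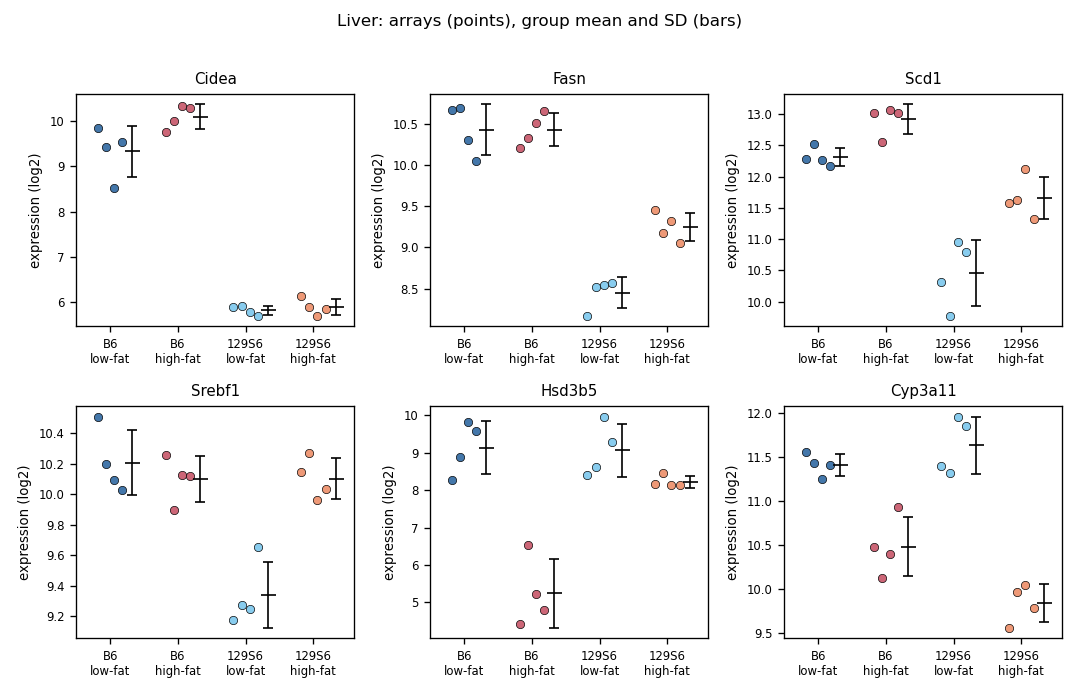
Expression in liver (log2, y axis) of Cidea, Fasn, Scd1, Srebf1, Hsd3b5 and Cyp3a11 in each array (points) of the 4 groups of strain and diet (x axis), with the group mean and SD as bars; n = 4 arrays per group. Cidea lies near 9.33 and 10.10 in the B6 groups against 5.82 and 5.89 in the 129S6 groups, and Hsd3b5 lies lowest in B6 mice on the high-fat diet.

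In muscle of B6 mice, the high-fat arrays had lower signals for many genes of oxidative phosphorylation and of glycolysis and glycogen metabolism than the low-fat arrays. Neither list's shift was called with an estimated correlation (adjusted p = 0.436 for both), and 75 genes were called in place of 2214 with the spread of each array as a covariate. Pgam2, the muscle phosphoglycerate mutase, had a mean of 11.94 ± 0.12 log2 units on the low-fat diet (SD, n = 3 arrays) and 8.19 ± 1.29 on the high-fat diet (SD, n = 4), a difference of -3.75 ± 0.72 (adjusted p = 0.00751). Other large decreases were in the actin-severing protein Gsn (-3.93 ± 0.78), the elongation factor Eef2 (-3.81 ± 0.73), the ribosomal protein Rps18 (-3.76 ± 0.80), the pyruvate kinase Pkm (-3.67 ± 0.86), Elob (-3.65 ± 0.61), Arf1 (-3.57 ± 0.82) and the complex I subunit Ndufb6 (-3.57 ± 0.52). The other Pkm probe set, at a mean of 9.92 against 11.56 log2 units, gave -0.52 ± 0.45 (adjusted p = 0.364 over all probe sets). Of 72 oxidative phosphorylation genes 43 were lower and 5 higher, 47 and 6 when adjusted over the list alone. Ndufa6 was at -1.64 ± 0.21 and Ndufa13 at -1.89 ± 0.29 (list camera adjusted p = 5.28e-15). Of 19 genes of glycolysis and glycogen metabolism 9 were lower and 1 higher, 15 and 1 when adjusted over the list alone. Among them were the insulin-responsive glucose transporter Slc2a4 (-2.03 ± 0.44) and the phosphofructokinase Pfkm (-3.11 ± 0.71), with camera adjusted p = 3.74e-07. Another Slc2a4 probe set, at 4.60 against 9.21 log2 units, gave 0.19 (adjusted p = 0.476). The largest increases were in Txnrd3 (1.69 ± 0.58), Uhmk1 (1.63 ± 0.47), Ccdc90b (1.49 ± 0.36), the transcription factor Mitf (1.34 ± 0.19) and Tspan8 (1.31 ± 0.28). Another Uhmk1 probe set, at a mean of 7.07 against 8.24 log2 units, gave -0.03 ± 0.33 (adjusted p = 0.951). Pdk4, a kinase that restrains glucose oxidation, was higher by 0.90 ± 0.28 (adjusted p = 0.0335). It was at 1.42 after quantile normalization and at 0.49 with the 3' to 5' signal as a covariate, where it and Txnrd3 lost their call (adjusted p = 0.155 and 0.0685), as without the arrays of high signal. Pdk4 also did with an intensity trend. Between the strains on the high-fat diet the same B6 arrays were lower for Ndufs3 (-3.75 ± 0.78), Gsn (-3.74 ± 0.72), Pgam2 (-3.66 ± 0.67), Elob (-3.61 ± 0.56) and Rps18 (-3.56 ± 0.74). They were higher for Gsdme (3.65 ± 0.83), Gas5 (2.73 ± 0.28), Tm2d1 (2.48 ± 0.71), Spg21 (2.45 ± 0.24) and the phospholipase Pla2g12a (2.44 ± 0.17). Other probe sets of Gsdme, at 4.83, and Pla2g12a, at 6.68 log2 units, gave 0.30 (adjusted p = 0.0815) and 0.54 (adjusted p = 0.395). Of the oxidative phosphorylation genes, 44 were lower and 3 higher there, 48 and 4 when adjusted over the list alone (camera adjusted p = 3.5e-14, and adjusted p = 0.496 with an estimated correlation).

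Limma called 2214 genes for diet in B6 muscle, 1220 higher and 994 lower. It called 2414 for strain on the high-fat diet, 1283 higher and 1131 lower in B6. Of 26 lists, 12 passed camera for the former and 10 for the latter, and 0 with an estimated correlation. The balance turned under other settings. For diet there were 869 higher and 892 lower after quantile normalization, 725 and 938 without the dimmest genes, and 901 and 1065 with only the 2 groups in the fit. For strain there were 810 and 1077 without the dimmest genes and 1070 and 1124 with probe sets specific to 1 gene. The arrays of the B6 high-fat group had a narrower spread over probe sets, with an SD of 1.639 ± 0.054 (n = 4) against 1.832 ± 0.036 (n = 3) on the low-fat diet (exact permutation test, two-sided p = 0.0286, the smallest possible, 0.129 after adjustment), and a Gapdh 3' minus 5' signal of 2.381 ± 0.964 against 0.631 ± 0.246. With the spread of each array as a covariate, 75 genes were called for diet in B6 and 134 for strain on the high-fat diet, and the difference in Txnrd3 was -0.015 for diet in B6. Of the genes named, 13 of 18 for diet and 6 of 11 for strain lost their call. The mean difference over the glycolysis and glycogen list then went from -1.78 to -0.13 (adjusted p = 0.484) and that over the oxidative phosphorylation list from -1.38 to -0.21 (adjusted p = 0.00593). For strain the latter went from -1.34 to -0.26 (adjusted p = 0.000378). The diet count was 188, 690, 1060 and 1033 without B6 low-fat replicates 13 and 14 and B6 high-fat replicates 6 and 7. The strain count was 1266, 1469, 1432 and 1196 without B6 high-fat replicates 6 and 7 and 129S6 high-fat replicates 3 and 4. Of 18 genes named for diet, 7 stayed past the threshold whichever array was left out, and of 11 for strain, 10 did.

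In muscle of 129S6 mice, limma called 0 genes for diet, and 151 had an unadjusted p under 0.05. The genes with the smallest p were Mest, an imprinted gene linked to fat mass (4.22 ± 0.11 on the low-fat and 5.24 ± 0.41 on the high-fat diet, SD, n = 4 arrays each; adjusted p = 0.992) and Ccdc50 (0.98 ± 0.23) with positive differences, and Kcna5 (-0.40 ± 0.10), Adh1 (-0.42 ± 0.10) and Tmed9 (-0.47 ± 0.14) with negative ones. No oxidative phosphorylation gene passed, over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05. Of 72 differences, 64 were positive. The list's shift was positive by camera (adjusted p = 4.33e-10, and adjusted p = 0.744 with an estimated correlation). Its mean difference went from 0.40 to 0.18 with the 3' to 5' signal and to 0.13 with the array spread as a covariate, and to -0.02 without 129S6 low-fat replicate 9, an array with an SD of 1.563. Among the 26 lists, 7 passed camera and 0 with an estimated correlation. The diet difference differed between the strains for 263 genes, led by Kcnma1 (1.91 ± 0.46), Gja1 (1.70 ± 0.40), Mitf (1.498 ± 0.26), S1pr1 (1.45 ± 0.31) and Klhl7 (1.32 ± 0.25) on the positive side. The negative side was led by Rps18 (-4.69 ± 1.10), Pkm (-4.62 ± 1.17), Pgam2 (-4.54 ± 0.99), Elob (-4.31 ± 0.83) and Gsn (-4.21 ± 1.06). The other Pkm probe set gave -1.06 ± 0.61 (adjusted p = 0.209 over all probe sets). Pkm lost its call after quantile normalization (adjusted p = 0.0525) and S1pr1 with probe sets specific to 1 gene (0.80, adjusted p = 0.122). All 10 lost it with the array spread as a covariate. Without the arrays of high 3' to 5' signal they did too, at similar differences (Elob -4.31). For this test 14 of 26 lists passed camera and 0 with an estimated correlation. The smallest p was that of oxidative phosphorylation, with 23 of 72 genes more negative in B6, and 47 more negative and 3 more positive when adjusted over the list alone (adjusted p = 5.08e-18, and adjusted p = 0.411 with an estimated correlation). The mean difference of that list went from -1.78 to -0.34 with the array spread as a covariate. The count of 263 (2907 by unadjusted p) was 5 with the array spread as a covariate. It was 0 without arrays of high 3' to 5' signal and 1494 with that signal as a covariate. With each array left out in turn it ranged from 2 to 862, and moved by over 1.5 times for 14 of 15 arrays. The diet differences in the 2 strains had a correlation of -0.504 across genes. That takes in 129S6 low-fat replicate 9, whose difference from its group had a correlation of 0.85 with the B6 diet difference. Opposite responses are not shown.

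On the low-fat diet, muscle differed between the strains in few genes. B6 muscle had the higher expression of the snoRNA host genes Snhg6 (3.62 ± 0.49, adjusted p = 0.00341) and Gas5 (3.44 ± 0.31, adjusted p = 0.000137), and of Spg21 (1.92 ± 0.26), Pla2g12a (1.87 ± 0.18), Serinc3 (1.77 ± 0.29), the complement regulator Cd59a (1.72 ± 0.19), Pla2g7 (1.70 ± 0.16) and Cxxc5 (1.44 ± 0.26). It had the lower expression of Gdpd3 (-2.49 ± 0.33), Ocel1 (-1.08 ± 0.14) and the alcohol dehydrogenase Adh1 (-0.70 ± 0.11). The other Pla2g12a probe set gave 0.96 ± 0.53 (adjusted p = 0.8 over all probe sets). Adh1 and Cxxc5 lost their call after quantile normalization, and these with Gdpd3, Ocel1 and Spg21 did with only the 2 groups in the fit. Ucp1, the uncoupling protein of brown adipocytes, was at 5.76 ± 0.18 log2 units in B6 (SD, n = 3 arrays) and 8.63 ± 1.47 in 129S6 muscle (n = 4), a difference of -2.86 ± 0.65 that did not pass (adjusted p = 0.132). On the high-fat diet it was at 5.74 ± 0.34 and 8.85 ± 1.01 (n = 4 each), a difference of -3.11 ± 0.60 that did (adjusted p = 0.00463). The other Ucp1 probe set, at a mean of 4.76 against 7.34 log2 units, did the reverse, with -1.502 ± 0.26 on the low-fat (adjusted p = 0.0224 over all probe sets) and -0.29 ± 0.24 on the high-fat diet (adjusted p = 0.337). With the array spread as a covariate the low-fat difference was -3.35 (adjusted p = 0.00663) and the high-fat difference, which rests on the narrow B6 arrays, -1.69 (adjusted p = 0.217). Limma called 23 genes on the low-fat diet, 20 higher and 3 lower, and 6 lists passed camera, 0 with an estimated correlation. Of the 23 genes, 15 were called in the same direction on the high-fat diet, 13 higher and 2 lower, where independent lists would share 3.11 and 0.411. The low-fat count was 9, 9, 11, 15 and 12 without B6 replicates 13, 14 and 15 and 129S6 replicates 11 and 12. The shared count was 8, 8 and 7 without those B6 arrays and 8, 7 and 23 without 129S6 low-fat replicates 11, 12 and 9.

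**Figure D2:**
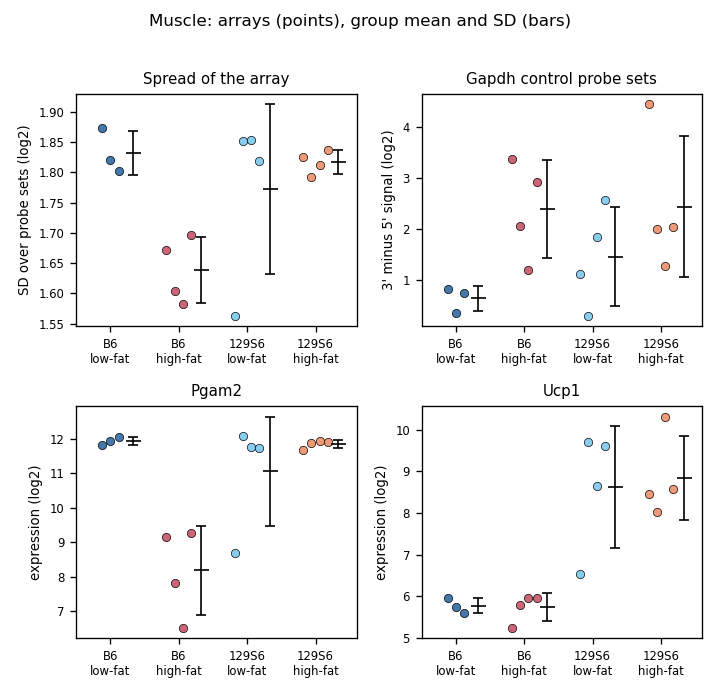
Values of each muscle array (points) in the 4 groups of strain and diet (x axis), with the group mean and SD as bars; n = 3 arrays for B6 on the low-fat diet and 4 for each other group. The panels plot the SD of each array over probe sets (log2), the 3' minus 5' signal of the Gapdh control probe sets (log2) and the expression of Pgam2 and Ucp1 (log2). The B6 high-fat arrays and 129S6 low-fat replicate 9, at 1.563, have the narrowest spread, and Pgam2 is lowest in them.

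In the fat of B6 mice, the high-fat diet came with higher expression of some fatty acid synthesis and chemokine genes. Neither list's shift was called with an estimated correlation (adjusted p = 0.325 and 0.358). The collagen cross-linking enzyme Lox (1.80 ± 0.24, adjusted p = 0.00889), the chemokine Cxcl9 (1.70 ± 0.32), Hpgd (1.64 ± 0.31) and Me1 (1.61 ± 0.24) rose. So did Gpam (1.44 ± 0.19, adjusted p = 0.00889), Lum (1.41 ± 0.25), Dhcr7 (1.34 ± 0.25) and Cytip (1.32 ± 0.22). Other probe sets of Lox, at 5.03 against 6.33, and Cytip, at 5.30 against 6.91 log2 units, gave 0.07 (adjusted p = 0.847 over all probe sets) and 0.68 (adjusted p = 0.327). Nnat (-3.03 ± 0.49, adjusted p = 0.0231), Ptges (-1.45 ± 0.22), Upk3b (-0.72 ± 0.13) and Pxmp2 (-0.60 ± 0.10) fell. Of 17 fatty acid synthesis genes 3 rose, Gpam, Me1 and Scd2 (1.14 ± 0.18), and 5 when adjusted over the list alone (camera adjusted p = 0.00783). The mean difference of this list went from 0.33 to 0.19 after quantile normalization (adjusted p = 0.0697) and to 0.503 with the 3' to 5' signal as a covariate (adjusted p = 1.37e-06). Of 26 chemokine and cytokine genes 3 rose, Ccl8 (1.13 ± 0.17), Ccl9 (1.26 ± 0.22) and Cxcl9, also 3 when adjusted over the list alone (adjusted p = 0.00771). Limma called 23 genes, 19 higher and 4 lower, and 1255 had an unadjusted p under 0.05. Of 27 lists, 12 passed camera and 0 with an estimated correlation. All B6 fat arrays are in series F1. With the series as a block, which changes the shared estimate of spread, 12 genes were called and the fatty acid synthesis and chemokine shifts each had adjusted p = 0.00777 by camera. The Gapdh 3' minus 5' signal was 2.207 ± 2.745 in the high-fat and 0.013 ± 0.054 in the low-fat arrays (SD, n = 4 each). The count was 1, 1, 5 and 9 without B6 low-fat replicates 1, 3, 4 and 5, and 39, 37 and 5 without high-fat replicates 6, 7 and 8. None of the 15 genes named stayed past the threshold whichever array was left out. The count was 182 without the arrays of high 3' to 5' signal and 1 with only these 2 groups in the fit, where all 15 lost their call. Ccl9, Cxcl9, Cytip, Dhcr7, Hpgd, Lum and Upk3b lost it under the block with the same differences. Cxcl9, Dhcr7 and Hpgd did with all probe sets, these with Cytip (0.68) and Upk3b with probe sets specific to 1 gene, Cxcl9 and Upk3b with the 3' to 5' signal as a covariate, Ccl9 after quantile normalization and 7 with an intensity trend.

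In the fat of 129S6 mice, the high-fat diet came with higher expression of some macrophage genes (5 of 32), the chemokine gene Ccl2 and, by 1 of 2 probe sets, leptin. The shift of the macrophage list was not called with an estimated correlation (adjusted p = 0.398). Lep, the adipocyte hormone leptin, rose from 11.22 ± 0.28 to 13.16 ± 0.22 log2 units (SD, n = 3 arrays each; 1.94 ± 0.20, adjusted p = 0.000817). In B6 mice the difference was 0.66 ± 0.18 (adjusted p = 0.155). The other Lep probe set, at a mean of 12.01 against 12.53 log2 units, gave 0.76 ± 0.49 in 129S6 (adjusted p = 0.494 over all probe sets) and 0.39 ± 0.42 in B6 mice (adjusted p = 0.636). The chemokine Ccl2 rose from 4.57 ± 0.35 to 7.18 ± 0.42 log2 units. Ptger3 (2.62 ± 0.46), Ctss (2.47 ± 0.39), Tyrobp (2.36 ± 0.41) and Lgals3 (2.35 ± 0.30) rose with it. So did Atf3 (2.25 ± 0.47), Aldh1a7 (2.17 ± 0.32) and Apobec1 (2.14 ± 0.23). The 2 other probe sets of Atf3 gave 0.21 ± 0.19 (adjusted p = 0.647 over all probe sets) and -0.10 ± 0.20 (adjusted p = 0.845). Nnat fell from 11.14 ± 0.14 to 7.38 ± 1.23 log2 units. Bcat2 (-2.98 ± 0.62), the adipokine Retn (-2.24 ± 0.35), Agt (-2.19 ± 0.30) and Tst (-1.98 ± 0.24) fell. Cyp2e1 (-1.93 ± 0.33), Ptges (-1.89 ± 0.25) and Hsd11b1 (-1.83 ± 0.29) fell too. Lgals3, Mpeg1 (2.01 ± 0.30) and Ctss led the macrophage genes, of which 13 rose and 1 fell when adjusted over the list alone (camera adjusted p = 4.96e-07). The macrophage gene Cd68 did not pass (0.78 ± 0.63, adjusted p = 0.593 over all probe sets). Of 23 white adipocyte genes 3 fell and 1 rose, 7 and 2 when adjusted over the list alone (adjusted p = 0.0247, and adjusted p = 0.398 with an estimated correlation). Its mean difference went from -0.68 to -0.44 with the 3' to 5' signal as a covariate (adjusted p = 0.000661). It was -0.30 without the arrays of high signal, which leaves high-fat replicate 14 alone.

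Limma called 62 genes for diet in 129S6 fat, 37 higher and 25 lower, and 19 higher and 25 lower with the 3' to 5' signal as a covariate. Of the lists, 11 passed camera and 0 with an estimated correlation. Of the 62 genes, 11 were called in the same direction in B6 fat, 7 higher and 4 lower, where independent lists would share 0.0852 and 0.0121. The diet differences of the strains had a correlation of 0.712 across genes. The test of their difference called 0 genes, with 232 at an unadjusted p under 0.05, and 5 lists by camera, 0 with an estimated correlation; Tst (1.70 ± 0.32) and Lep (-1.27 ± 0.27, adjusted p = 0.722 for both) were among those with the smallest p. Tst passed with the 3' to 5' signal as a covariate (1.55, adjusted p = 0.0165) and Lep after quantile normalization (-1.48, adjusted p = 0.0475). The other Lep probe set gave -0.37 ± 0.65 (adjusted p = 0.997 over all probe sets). With the array series as a block, and likewise within series F2, which holds 2 low-fat and all high-fat arrays, 11 genes were called, with Lep (1.82, adjusted p = 0.00934), Scd2, Lgals3, Apobec1, Agt, Tst and Ptges among them. Nnat (-3.77, adjusted p = 0.0592), Ccl2 (2.55, adjusted p = 0.0666) and Ctss (2.34, adjusted p = 0.0814) were not called. Of the 19 genes named, 11 lost their call under the block, and all 11 kept their direction. Bcat2 (-1.74), Atf3, Ptger3 and Tyrobp lost it with the 3' to 5' signal as a covariate, Atf3 and Bcat2 with all probe sets, and Atf3 and Tyrobp with only the 2 groups in the fit. Nnat was at -2.49 without the arrays of high 3' to 5' signal, which leaves high-fat replicate 14 alone. The macrophage shift had adjusted p = 2.09e-06 by camera under the block. The Gapdh 3' minus 5' signal was 4.035 ± 3.177 in the high-fat and 0.165 ± 0.084 in the low-fat arrays (SD, n = 3 each). The count was 11, 11, 29, 32, 34 and 175 without low-fat replicates 9, 10 and 11 and high-fat replicates 12, 13 and 14. The shared count was 1, 1, 1, 4, 2, 5, 5, 7 and 7 without B6 low-fat replicates 1, 3, 4 and 5, B6 high-fat replicate 8, 129S6 low-fat replicates 9 and 10 and 129S6 high-fat replicates 12 and 13. Without B6 high-fat replicate 7 the test of the difference called 6 genes. Of 19 genes named for diet in 129S6 fat, 7 stayed past the threshold whichever array was left out.

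Between the strains, fat of B6 mice on the low-fat diet had the higher expression of some macrophage genes (5 of 32) and, by 1 of 2 probe sets, leptin. Ccl2 was at 7.67 ± 0.32 log2 units in B6 (SD, n = 4 arrays) and 4.57 ± 0.35 in 129S6 mice (n = 3), a difference of 3.10 ± 0.37 (adjusted p = 0.00102). The macrophage elastase Mmp12 (3.14 ± 0.38), Lgals3 (2.58 ± 0.28), AI506816 (2.49 ± 0.43), Ctss (1.94 ± 0.36), Lep (1.24 ± 0.19), Npy (2.00 ± 0.32), Gas5 (3.36 ± 0.44) and Snhg6 (1.97 ± 0.30) were higher as well. Gdpd3 (-3.16 ± 0.24), Pck1 (-2.58 ± 0.37), Hal (-2.39 ± 0.18) and S100a1 (-2.21 ± 0.24) were lower. So were Hbb-b2 (-2.11 ± 0.25), Erdr1 (-2.00 ± 0.27), Cidea (-1.88 ± 0.30) and Bckdhb (-1.83 ± 0.28). The other Lep probe set gave 0.91 ± 0.46 (adjusted p = 0.656 over all probe sets). Of the macrophage genes 9 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 3.25e-15, and 0.0329 with an estimated correlation). Cd68 did not pass (1.41 ± 0.59, adjusted p = 0.517 over all probe sets). Of 17 fatty acid synthesis genes 1 was lower, Gpam (-1.07 ± 0.21), and 6 when adjusted over the list alone (adjusted p = 0.000183, and adjusted p = 0.0859 with an estimated correlation). No gene of epididymis and testis passed, over all genes or adjusted over the list alone, and 5 higher and 1 lower had an unadjusted p under 0.05. Of the 17 differences, 15 were positive and the list shifted up by camera, with a median of 0.85 (adjusted p = 8.18e-05, and 0.0329 with an estimated correlation). On the high-fat diet Igkv6-23 (3.28 ± 0.64), AI506816 (3.19 ± 0.43), Gas5 (2.68 ± 0.44), Snhg6 (2.51 ± 0.30), Dnajb9 (2.02 ± 0.40) and Ccl8 (1.96 ± 0.18) were higher in B6. Gdpd3 (-3.79 ± 0.24), Hal (-3.04 ± 0.18), Ucp1 (4.97 ± 0.14 log2 units in B6 and 7.53 ± 0.72 in 129S6; -2.56 ± 0.35), Erdr1 (-2.27 ± 0.27), the interferon-inducible Ifi202b (-1.93 ± 0.14) and Gbp2b (-1.92 ± 0.24) were lower. Lep differed by -0.04 ± 0.19 there and by 0.53 ± 0.46 by its other probe set (adjusted p = 0.774 over all probe sets). The lists with the smallest p there were the hepatocyte genes, none of which passed and of which 4 of 19 were lower when adjusted over the list alone (camera adjusted p = 3.62e-06, and adjusted p = 0.247 with an estimated correlation), and the macrophage genes, 1 of which was higher, 4 when adjusted over the list alone (3.98e-06 and 0.153). The hepatocyte list's mean difference of -0.66 was -1.04 without the arrays of high 3' to 5' signal, which leaves 129S6 high-fat replicate 14 alone. It was -1.68 with the array series as a block, set by 129S6 low-fat replicate 9, highest in Alb. Another Erdr1 probe set, at a mean of 7.56 against 7.58 log2 units, gave -0.11 on the low-fat (adjusted p = 0.975 over all probe sets) and 0.08 on the high-fat diet (adjusted p = 0.913). Another Dnajb9 probe set, at 6.36 against 6.45, gave -0.16 on the high-fat diet (adjusted p = 0.934). With only the probe sets specific to 1 gene, AI506816 (at 5.00 against 9.085 log2 units) gave 0.32 on the low-fat (adjusted p = 0.715) and -0.099 on the high-fat diet. S100a1 (at 4.15 against 8.39) gave -0.03 on the low-fat diet (adjusted p = 0.996).

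Limma called 89 genes between the strains in fat on the low-fat diet, 33 higher and 56 lower in B6, and 36 on the high-fat diet, 25 higher and 11 lower. Of 27 lists, 12 and 14 passed camera on these diets, and 2 and 0 with an estimated correlation. Without the arrays of high 3' to 5' signal, 129S6 high-fat replicate 14 stands alone, so no split is given. With all arrays, 22 were called on both diets in the same direction, 12 higher and 10 lower, where independent lists would share 0.1 and 0.0747. With the array series as a block, both strain comparisons rest on 129S6 low-fat replicate 9, the only 129S6 array in series F1. It also held epididymis and liver transcripts (Gpx5 at 10.81, Alb at 11.12), so only differences are given. On the low-fat diet the block gave Gdpd3 (-3.30), Hal (-2.47), Mmp12 (3.42), Lgals3 (2.93), Ccl2 (3.20), Lep (1.46), Gas5 (3.45) and Pck1 (-2.37). On the high-fat diet it gave Gdpd3 (-3.99), Hal (-3.16), Ifi202b (-1.92), Erdr1 (-2.12), Gbp2b (-2.30) and Ucp1 (-1.89). Higher on that diet were Gas5 (2.82), Snhg6 (2.62), Ccl8 (1.97), Dnajb9 (1.86), AI506816 (2.56), Igkv6-23 (2.17) and Lep (0.30). There AI506816, Dnajb9, Gas5, Gbp2b, Igkv6-23 and Snhg6 lost their call with only the 2 groups in the fit, and Dnajb9 and Igkv6-23 did after quantile normalization. The mean difference of the low-fat macrophage list went from 0.91 to 1.035 under the block. The latter sets B6 mice against 129S6 replicate 9 alone, and series F1 holds no 129S6 array on the high-fat diet. The low-fat count was 54, 55, 59, 31, 40 and 38 without B6 replicates 1, 3 and 5 and 129S6 replicates 9, 10 and 11. The high-fat count was 897 without B6 replicate 7 and 23 without B6 replicate 8. The shared count was 44 without B6 high-fat replicate 7 and 14 without 129S6 low-fat replicate 10 or 11. The Gapdh 3' minus 5' signal was 6.03, 5.81 and 5.93 in B6 high-fat replicate 7 and 129S6 high-fat replicates 12 and 13; with it as a covariate the counts were 344 and 195.

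**Figure D3:**
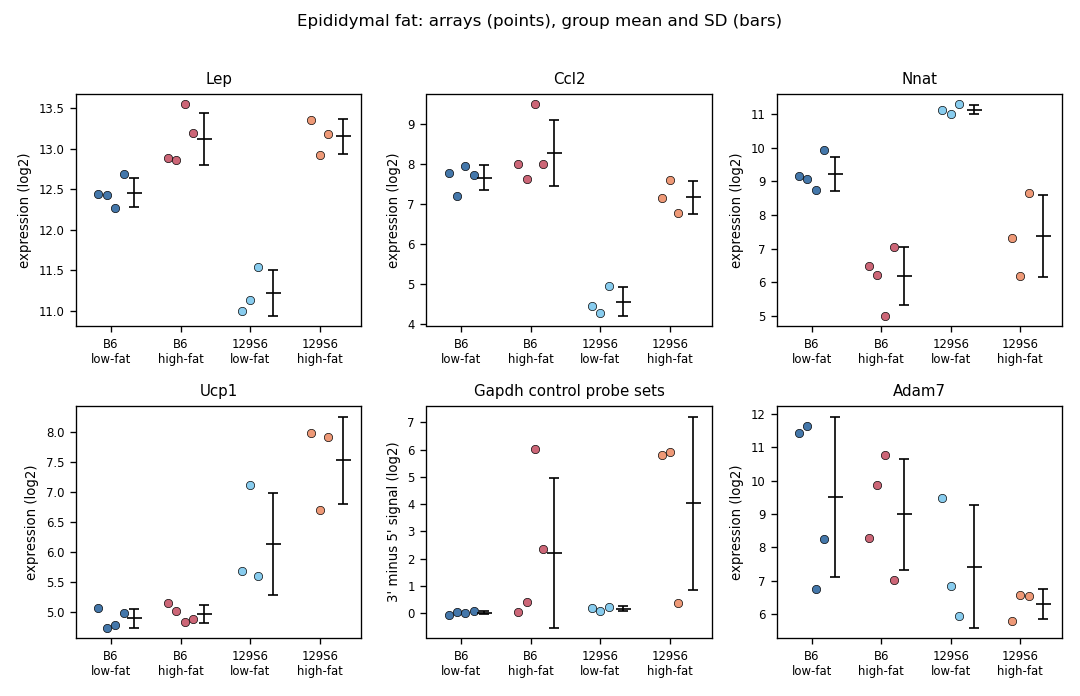
Values of each epididymal fat array (points) in the 4 groups of strain and diet (x axis), with the group mean and SD as bars; n = 4 arrays for each B6 group and 3 for each 129S6 group. The panels plot the expression (log2) of Lep, Ccl2, Nnat, Ucp1 and the epididymis gene Adam7 and the 3' minus 5' signal of the Gapdh control probe sets (log2). Lep and Ccl2 are lowest in 129S6 mice on the low-fat diet, with means of 11.22 and 4.57.

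With both diets averaged, 12 genes differed between the strains in the same direction in all 3 tissues, where independent lists would share 0.204 higher and 0.0495 lower. The 9 higher in B6 were led by Gas5 (2.99, 3.08 and 3.02 log2 units in liver, muscle and fat). Next were Snhg6 (1.80, 2.28 and 2.24), Cd59a (1.54, 1.86 and 1.38), Spg21 (2.42, 2.18 and 1.25), Abcd3 (1.93, 0.89 and 1.00) and Pttg1 (0.81, 1.08 and 0.80). The 3 lower were Gdpd3 (-2.14, -2.63 and -3.47), Ocel1 (-1.02, -0.999 and -1.16) and Bckdhb (-0.49, -0.96 and -1.80). Counting calls in at least 2 tissues, 110 genes had the same direction, and 46 had opposite directions. With only the probe sets specific to 1 gene, Gas5 rests on a dim probe set (4.15 to 4.36 against 6.91 to 7.38 log2 units), so a lost call decides little. It lost its call in liver (0.09 and 0.07) and fat (0.27 and 0.28) on both diets and in muscle on the low-fat diet (0.08). In muscle on the high-fat diet it was at 0.46 (adjusted p = 0.0473). Within a tissue, 64 called differences above are of genes with another probe set. In 18 another passed in the same direction and in 46 none did. The count of 12 was 25 without muscle 129S6 low-fat replicate 9. The series block acts on fat alone here and rests on 1 129S6 array, so its count is left out.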

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

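The 3 tests of the muscle pattern and, in B6 liver, the tests of the high-fat diet and of degradation and array spread by a covariate were chosen after the results were seen; the other tests here were set before. Each array was compared with the others of its group where a group had 4, by the gap to its nearest neighbour against the range of the group. Of 67 such groups of values 7 had an array apart, and chance gives about 1 in 20. Over all named genes 52 of 477 groups (10.9%) did, 18 of them by 129S6 low-fat replicate 9 in muscle. In liver, Hsd3b5 was at 8.473 in 129S6 high-fat replicate 8 (others 8.134 to 8.18), Scd1 at 12.561 in B6 high-fat replicate 14 (13.017 to 13.064), Fasn at 8.174 in 129S6 low-fat replicate 5 (8.52 to 8.565) and the Gapdh 3' minus 5' signal at 3.264 in 129S6 low-fat replicate 11 (0.13 to 0.406). In muscle, 129S6 low-fat replicate 9 stood apart in Pgam2, at 8.701 (11.728 to 12.072), in Mest, at 4.052 (4.262 to 4.291), and in the SD of the array, at 1.563 (1.819 to 1.854).

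The diet difference differed between the strains, by the test of the difference itself, for 453 genes in liver and 263 in muscle. The liver genes named were Col4a1 (1.935), H2-Q1 (1.763), Apoa4 (1.595), Cd99 (1.499), Gja1 (1.286), Fasn (-0.797), Srebf1 (-0.874), Pltp (-0.941), Mid1ip1 (-1.506), Sec14l2 (-1.705), Sod1 (-2.014), Hsd3b5 (-3.051) and Actb (-3.781). In muscle they were Kcnma1 (1.908), Gja1 (1.699), Mitf (1.498), S1pr1 (1.45), Klhl7 (1.323), Gsn (-4.208), Elob (-4.313), Pgam2 (-4.541), Pkm (-4.615) and Rps18 (-4.686).

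In muscle, 2214 genes were called for diet in B6 and 2414 for strain on the high-fat diet, and both comparisons rest on the B6 high-fat arrays, whose spread was narrow. RNA degradation as the whole cause is argued against by the count of 2982 genes for diet in B6 with the 3' to 5' signal as a covariate. A compression of the signal over these arrays is a candidate explanation: across genes, which are not independent replicates, the diet difference in B6 had a correlation of 0.85 with the difference of 129S6 low-fat replicate 9, the other narrow array, from the rest of its group, and the other arrays of that group gave -0.15 to 0.29. An effect of the diet stays open. With the array spread as a covariate 75 genes were called, and since all 4 B6 high-fat arrays are narrow, that fall does not exclude it.

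In B6 liver, 1502 genes were called for diet. Degradation of the low-fat arrays as the whole cause is argued against by the count of 1630 genes with the 3' to 5' signal as a covariate, which moved the count for the difference between the strains from 453 to 1073. The correlation across genes with the difference of the other 129S6 low-fat arrays from replicate 11 was 0.19, between the bounds set for it, so degradation stays open. The other arrays gave -0.16 to 0.12. A part by the array spread stays open too: each low-fat array was wider than each high-fat array, and with the spread as a covariate 1047 genes were called. Array series L1 holds all B6 low-fat arrays and no other, so series and diet cannot be told apart; within 129S6 low-fat arrays, 1015 genes differed between series L3 and L2 (2 arrays against 2). The L3 pair there holds replicate 11, with its Gapdh 3' minus 5' signal of 3.264, and had the muscle actin Acta1 at 8.682 and 8.17 against 6.215 and 6.005 in the L2 pair, so the series cannot be told apart there from degradation and muscle transcripts. The diet also stays open: the diet differences in B6 and 129S6 had a correlation of 0.12 across genes, and the strains may respond differently.

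In at least 2 tissues, 110 genes differed between the strains in the same direction. A sequence variant under the probes might give such a difference, as might a difference in expression, and they cannot be told apart here. For the 32 genes with another probe set, the median ratio of its strain difference to that of the probe set used was 0.14 (quartiles 0.01 and 0.31), with 21 under 0.25 and 6 at 0.5 or more. A ratio under 0.25 had been set as a bound against a difference in expression. That bound was wrong, because genes called for diet in B6 liver, where no sequence differs, had a median ratio of 0.07 (quartiles -0.24 and 0.49, 423 genes); this was decided after the value was seen.

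The arrays of each comparison were also split in other ways into groups of the same sizes. In liver, 1 of 35 splits gave as many genes for diet in B6 (1502, highest other 0), for strain on the low-fat diet (1142, highest other 564) and for strain on the high-fat diet (426, highest other 1). For the difference between the strains 2 of 100 did (453, highest other 552). These shares are under the bound. The split with 552 parted the B6 arrays by diet and, among the 129S6 arrays, set low-fat replicates 11 and 12 and high-fat replicates 8 and 9 against the rest. For diet in 129S6, 2 of 35 did, a share over the bound. The real count was 19. The same split of the 129S6 arrays gave 916, which points to a structure of the samples that sets these arrays apart. The count with the series as a block was 10. In muscle, shares were under the bound for diet in B6 (1 of 35, 2214, highest other 1069), strain on the high-fat diet (1 of 35, 2414, highest other 0) and the difference between the strains (4 of 100, 263). For the last, exchanging 129S6 low-fat replicates 10 and 11 for high-fat replicates 3 and 4 gave 1526, which points to a structure of the samples. The share was over the bound for diet in 129S6 (35 of 35, 0, highest other 1) and strain on the low-fat diet (2 of 35, 23, highest other 39). In fat, the share was under it for diet in B6 (1 of 35, 23, highest other 15) and strain on the low-fat diet (1 of 35, 89, highest other 2). The 10 splits for diet in 129S6 are too few for a share under 0.05; the real count was 62 and the highest other 0. The share was over the bound for the difference between the strains in fat (100 of 100, 0, highest other 342) and for strain on the high-fat diet (4 of 35). In the latter the real count was 36. A split that grouped B6 replicate 7 with 129S6 replicates 12 and 13, the arrays of high 3' to 5' signal, gave 2830, which points to a structure of the samples.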

How the results depend on the processing

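The settings with the 3' to 5' signal, the array spread and the arrays of 1 series were chosen after seeing the data. No paired analysis was possible because replicate numbers are not shared between the groups of a tissue. Of 222 named differences under 3860 alternatives, 3236 kept their side of the threshold, 609 fell short of it, 12 came to pass it and 3 reversed. Direction was compared only where the main fit or the alternative passed, so a difference that passed in neither could change sign and count as kept. The 3 were Tnnc2 in liver for diet in B6, -0.042 with probe sets specific to 1 gene, Txnrd3 in muscle for diet in B6, -0.015 with the array spread as a covariate, and AI506816 in fat for strain on the high-fat diet, -0.099 with probe sets specific to 1 gene. Of 32 list shifts under 459 alternatives, 419 kept their direction and side of the threshold, 38 fell short and 2 reversed, the proteasome for diet in B6 liver, at 0.047 with the array spread as a covariate, and oxidative phosphorylation for diet in 129S6 muscle, at -0.02 without 129S6 low-fat replicate 9, the lowest of the values with each array left out, and at most 0.559, without replicate 11. With fry, the list shifts of skeletal muscle genes for diet in B6 liver (0.0607), of macrophage (0.235) and interferon response genes (0.102) for strain on the high-fat diet in liver, of glycolysis in B6 (0.0563) and oxidative phosphorylation in 129S6 muscle (0.857) for diet, of oxidative phosphorylation for the difference between the strains in muscle (0.0999), of chemokines in B6 (0.0633) and white adipocyte genes in 129S6 fat (0.214) for diet, and of macrophage (0.104) and hepatocyte genes (0.129) for strain on the high-fat diet in fat had an adjusted p past 0.05. The cause was not tested except where the setting itself removes arrays or genes.

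Counts that moved by over 1.5 times follow, and the cause of each was not tested. With all probe sets, liver diet calls shared by the strains were 7, muscle diet in B6 3331, fat strain on the high-fat diet 56 and strain calls shared by the tissues 20, where more is tested. With probe sets specific to 1 gene, fat diet in B6 was 13. With quantile normalization, the liver difference between the strains was 283, muscle strain on the low-fat diet 15, the fat difference between the strains 1 and fat shared diet calls 18. With an intensity trend and robust prior, liver shared diet calls were 7, fat diet in B6 13 and fat shared diet calls 7.

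With only the 2 groups compared, liver diet in 129S6 was 4, strain on the low-fat diet 500, strain on the high-fat diet 914 and shared diet calls 3. Muscle strain on the low-fat diet was 6 and shared strain calls 5. Fat diet in B6 was 1, diet in 129S6 186, strain on the low-fat diet 743, strain on the high-fat diet 9, shared diet calls 0 and shared strain calls 9. With the array series as a block, liver diet in 129S6 was 10 and strain on the high-fat diet 167. Fat diet in B6 was 12, diet in 129S6 11 and shared diet calls 5. The strain counts of fat, and those shared by the tissues, rest on 1 array there and are left out. Within 1 array series, diet in 129S6 was 12 in liver and 11 in fat.

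With the 3' to 5' signal as a covariate, liver strain on the high-fat diet was 732 and the difference between the strains 1073, and the latter was 1494 in muscle. Fat diet in B6 was 38, strain on the low-fat diet 344, strain on the high-fat diet 195, the difference between the strains 4 and shared strain calls 83, and strain calls shared by the tissues were 26. Without arrays of high 3' to 5' signal, liver strain on the low-fat diet was 1933, strain on the high-fat diet 762, the difference between the strains 849 and shared strain calls 256, and the muscle difference between the strains was 0. Fat diet in B6 was then 182, diet in 129S6 137, strain on the low-fat diet 673, strain on the high-fat diet 128, the difference between the strains 4, shared diet calls 51 and shared strain calls 88; 129S6 high-fat fat keeps 1 array there, assumed to vary like the others. With the array spread as a covariate, liver diet in 129S6 was 31, strain on the low-fat diet 462, strain on the high-fat diet 887 and the difference between the strains 913, and muscle diet in B6 was 75, strain on the low-fat diet 51, strain on the high-fat diet 134 and the difference between the strains 5.

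Leaving out each array in turn gave, in liver, 842 to 1429 for diet in B6, 2 to 23 for diet in 129S6, 560 to 1933 for strain on the low-fat diet, 249 to 319 for strain on the high-fat diet, 263 to 849 for the difference between the strains, 2 to 14 shared diet calls and 109 to 176 shared strain calls. In muscle it gave 188 to 2505, 0 to 0, 9 to 33, 1196 to 2713, 2 to 862, 0 to 0 and 7 to 23 in the same order. In fat it gave 1 to 39, 11 to 175, 31 to 64, 23 to 897, 0 to 6, 1 to 13 and 14 to 44. Strain calls shared by the tissues ranged from 8 to 25. Of differences of 1 log2 unit put into simulated data, between 46.3% (muscle, difference between the strains) and 97% (liver, diet in 129S6) were called, so smaller differences can be missed.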

Other observations

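Every B6 fat array carried transcripts of the epididymis or testis (Adam7 or Prm1 above 8 log2 units). Of the 129S6 arrays only low-fat replicate 9 and high-fat replicate 12 did, so strain and this carry-over largely run together. The 4 given were chosen afterwards from a list fixed beforehand. Adam7 and Gpx5 were at 11.43 and 11.91 log2 units in B6 low-fat replicate 1, 11.63 and 11.88 in replicate 3, 9.87 and 10.59 in B6 high-fat replicate 6, 10.77 and 11.85 in replicate 7 and 9.47 and 10.81 in 129S6 low-fat replicate 9, while Gpx5 was at most 5.98 in the other fat arrays, of which B6 low-fat replicate 5 and B6 high-fat replicate 2 had Adam7 at 8.255 and 8.28. Prm1 and Tnp2, sperm precursor transcripts, were at 11.29 and 11.25, 10.27 and 10.21, 8.37 and 8.61 in B6 low-fat replicates 4, 5 and 1. In B6 high-fat replicates 2, 6, 7 and 8 they were at 10.34 and 10.94, 8.79 and 8.80, 9.48 and 6.43, 8.98 and 9.58. In 129S6 high-fat replicate 12 they were at 8.45 and 7.98. The liver transcript Serpina1b ran with strain, at 8.80 to 10.85 in 129S6 and 6.335 to 8.73 in B6 fat arrays. Alb reached 11.12 in 129S6 low-fat replicate 9 and 10.19 in high-fat replicate 14. Acta1 in liver also reached 7.48 in B6 low-fat replicate 4.

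The first principal component held 33.5% of the variance in liver, 64.1% in muscle and 49% in fat. Pearson correlations between arrays of 1 group, across probe sets, ranged from 0.891 to 0.995, and among all pairs of arrays 0 were identical.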
